A study of Caenorhabditis elegans with 4 samples.

How the data were processed

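Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Caenorhabditis elegans hermaphrodites at the L2 larval stage. The strain, OP57, carries a transgene that expresses the transcription factor SEM-4 fused to GFP, so that chromatin bound by the fusion protein can be collected with an antibody to GFP. The 4 samples are 2 ChIP libraries and 2 input libraries, and the sample titles number both kinds 1 and 2. Per the labels' protocols, synchronised worms were grown at 20 °C, crosslinked with 2% formaldehyde and sonicated, and 10% of the cleared extract was kept as the input, the whole genomic DNA that serves as the control. No label says whether the replicates were separate cultures, so agreement between them may be biological or technical.

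The data were 3 lists of called regions, 1 for each ChIP library and a combined list for the series. Per the file headers, coordinates are on WormBase WS220 and the regions are PeakSeq calls. PeakSeq compares a ChIP library with a control and reports regions in which the ChIP reads are in excess. Each deposited region has a start, an end and a q-value, which the authors left with no further scaling. The largest q-value in any list was 0.00998, so a limit of 0.01 fits all of them. Comment lines in the deposited files show that coordinates were carried over to WS220 from another build, with 4 regions changed in replicate 1, 5 in replicate 2 and 5 in the combined list. The PeakSeq version, the aligner, the read filters, the original build, the control used for each list and the way in which the replicates were combined are not given in the sources used here. The lists hold no read counts and no fold enrichment. Sequencing depth is therefore unknown, and a low q-value can come from stronger enrichment or from more reads. The regions within 1 list did not overlap each other.

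Regions were ranked within their list by q-value, and strength is given as −log10 of the authors' q-value. Overlap meant at least 1 shared base pair. Overlap counts were made with bedtools 2.31.1 and equalled those of the functions used for the random placements. The other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Overlap between lists was compared with 1000 random placements of 1 list, in which each region kept its width and chromosome. The one-sided p is the share of placements with as much overlap, and 0.001 is the smallest value they can give. Differences of medians and correlations across regions were tested with 100000 permutations, two-sided, with 1e-05 as the smallest possible p. Regions are not independent replicates, so all p-values over regions, those of Fisher and binomial tests included, describe the lists and not a population of worms. Shares of regions have 95% Wilson intervals, which cover counting error only.

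Chromosome lengths for WS220 were not used here. Each chromosome's span was taken as position 1 to the end of its last region in any of the 3 lists, from 13.8 Mb for chromosome III to 20.9 Mb for chromosome V, 100.2 Mb in all. The number of regions on X was compared with the share of the span on X, and the number with a midpoint in the central 50% of each chromosome with 50% of the regions, by exact binomial tests. The overlap and rank computations were tested on simulated lists, and the X share on a simulated count. With 60% of 2527 simulated regions planted as exact copies from the other list, 60.2% were recovered after correction for chance overlap. The overlap shares in the results have no such correction. With a rank correlation of 0.65 planted over 1516 pairs, 0.65 was recovered. For 1 random count of regions on X out of 7554, with the X share planted at 0.8 of the span share, 0.81 was recovered.

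The tests, the regions to be named and most alternatives were chosen before the data were examined. The named regions were the 15 combined regions with the lowest q-values among those overlapping both replicates, and the 3 with the lowest q-values among those overlapping neither. Regions named for other reasons were chosen after their values were seen. Alternatives were a stricter overlap, lists of equal length, the top 50% of each list, each replicate list in place of the combined one and counts of occupied 100 kb bins. Added after the data were seen were circular shifts of a list along its chromosomes, permuted 1 Mb bins, and removal of chromosome I, of regions under 50 bp or of extreme pairs. The tests of chromosome I against the others and of the central share of autosomes against X were also added then. Planned tests of genomic features, gene lists and gene families were not carried out. They need an annotation on WS220, and the gene table at hand is on another assembly (WBcel235) and gives no strand. For this reason regions are named by position and no gene is assigned to them. The transgene adds copies of sem-4 and unc-119 sequence, and the regions at those loci were not identified here.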

Results

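SEM-4 is a zinc-finger transcription factor of the Spalt family that acts in the development of neurons, vulval precursors and mesoderm in C. elegans. The study asked where in the genome SEM-4 tagged with GFP is bound in L2 larvae. Binding was described by 5386 called regions in ChIP replicate 1, 2527 in replicate 2 and 7554 in the combined list. The regions covered 2.36 Mb, 1.40 Mb and 3.56 Mb. Their median widths were 339 bp, 431 bp and 357 bp, and the widest reached 19807 bp, 14267 bp and 26501 bp. Depth is not recorded in these lists, and the input libraries enter only through the authors' calls.

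The strongest regions of the combined list were broad and spread over all 6 chromosomes. Among the 15 combined regions with the lowest q-values that were called in both replicates, 4 lay on chromosome I, 4 on III, 3 on X, 2 on II, 1 on IV and 1 on V. Their median width of 5798 bp was 16.24 times the median of the whole combined list. Width and q-value went together throughout that list. Median autosomal width fell from 843 bp in the strongest of 10 equal classes of −log10 q to 200 bp in the weakest. The breadth of the 15 is therefore not independent of their choice by q-value. The 15 ranked from 2 to 36 in replicate 1 (median 9) and from 2 to 180 in replicate 2 (median 14). The region that ranked 1 in both replicates, on chromosome V from 6221388 to 6231164 in replicate 1, has no overlap in the combined list and so is not among the 15. All q-values and positions are the authors' own.

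The lowest q-value in the combined list, 9.44e-247, belonged to a region of 12993 bp on chromosome II, from 10541856 to 10554848. It was split into 5 regions in replicate 1, the best of which ranked 4 (q = 6.50e-113), and 2 in replicate 2, the best of which ranked 7 (q = 7.41e-51). The next was on X at 16929337 to 16932599 (q = 8.24e-224), and its best overlapping region ranked 2 in both replicates. A broad region on X, from 4142009 to 4149230 (q = 2.75e-198), ranked 3 in replicate 1 and 8 in replicate 2. A region of 2264 bp on IV, from 14032444 to 14034707 (q = 3.31e-169), ranked 5 and 3 in the replicates. The shortest of the 15, on X from 14525341 to 14526340 (q = 1.22e-125), was 1000 bp wide and ranked 8 and 9.

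On chromosome III, a pair of neighbouring regions from 13060632 to 13066399 and from 13066733 to 13072530 ranked 6 and 8 in the combined list. They ranked 6 and 7 in replicate 1, and their best parts ranked 19 and 25 in replicate 2. Also on III were regions from 8799646 to 8802744 and from 12611863 to 12616392, with combined q-values of 1.21e-154 and 3.15e-128. The latter ranked 4 in replicate 2 (q = 2.45e-62). Chromosome II held a second region of the 15, from 8741254 to 8748241 (q = 2.18e-134), which ranked 11 in replicate 1 and 14 in replicate 2. Chromosome V held 1, from 14363268 to 14369160 (q = 6.35e-138), which ranked 27 and 82.

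By the best overlapping region in each replicate list, 11 of the 15 ranked lower in replicate 2 than in replicate 1. These were all 4 on chromosome I and 7 of the other 11. The widest region in every list was among the 4 on chromosome I. It spanned 26501 bp in the combined list, from 7024272 to 7050772 (q = 6.20e-158), 19807 bp in replicate 1 and 14267 bp in replicate 2, where it ranked 24 and 41. Its neighbour from 7078652 to 7085208 ranked 9 in replicate 1 and 55 in replicate 2. The regions from 5372068 to 5378931 and from 7656186 to 7661323 ranked 36 and 14 in replicate 1, and 180 and 90 in replicate 2. For the region at 5372068, the ranks come from parts that do not overlap: 5372202 to 5376022 in replicate 1 and 5376879 to 5378013 in replicate 2. The transgene adds copies of sem-4 and unc-119 sequence. Those loci were not identified, so it is not known whether the widest region or any other of the 15 lies there.

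The comparison of the replicates asked whether the same places were bound in both. Nearly all of the 500 strongest regions of each list were shared. Regions called in replicate 1 alone were mostly weak within the replicate 1 list. Of the 2527 regions of replicate 2, 2189 overlapped a replicate 1 region, or 86.6% (95% Wilson interval 85.2 to 87.9). Random placement gave 5.39% on average and at most 6.93% (one-sided permutation p = 0.001, the smallest possible). Of the 5386 regions of replicate 1, 2166 overlapped replicate 2, or 40.2% (38.9 to 41.5), against 2.58% by chance. Replicate 1 had 3220 regions with no counterpart, and replicate 2 had 338. This contrast follows the lengths of the lists, because 2189 regions of replicate 2 matched 2166 of replicate 1. Lists of equal length must then give similar shares, so a cut to equal length shows only the level of sharing. With both cut to the strongest 2527, the shares were 66.6% of replicate 1 and 68.0% of replicate 2. No counterpart was found for 844 and 809 regions.

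Sharing depended on strength. All 100 of the strongest regions of replicate 1 were found in replicate 2, as were 489 of its top 500 and 1478 of its top 2000. In the other direction the numbers were 99 of 100, 499 of 500 and 1821 of 2000. In replicate 1, the median −log10 q was 5.69 for shared and 2.73 for unshared regions, and the median widths were 469 bp and 269 bp. In rank percentile, where 100 is the strongest, the shared regions lay 42.7 points higher in replicate 1 and 33.3 points higher in replicate 2 (permutation test of medians, two-sided p = 1e-05 for both). The strongest replicate 1 region without a counterpart, on II from 11746641 to 11748615, ranked 274 (q = 3.59e-15). One exception in replicate 2 had a low q-value (q = 6.57e-42, rank 13). It was a region of 3642 bp at the right end of chromosome I, from 15064007 to 15067648, and overlapped nothing in replicate 1. Repeat content and mappability there were not examined. The next unshared region of replicate 2 ranked 614.

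Regions that were strong in one replicate were also strong in the other, at lower values in replicate 2. Over 2218 pairs of overlapping regions, Spearman's rho of −log10 q was 0.67 and Pearson's r of its logarithm was 0.75 (permutation p = 1e-05 for both). These are correlations across regions of 1 pair of libraries. Replicate 2 had the lower −log10 q in 79.6% of the pairs, and the median ratio of replicate 2 to replicate 1 was 0.69.

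**Figure D1:**
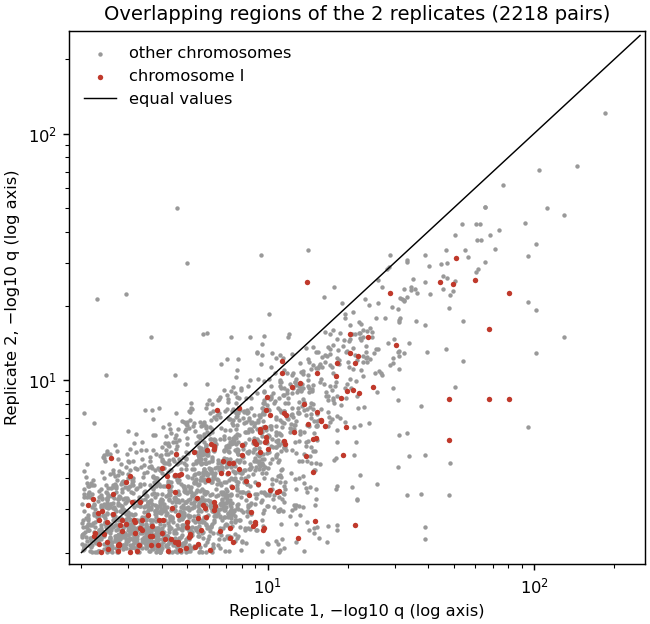
The −log10 q of each of 2218 pairs of overlapping regions in replicate 1 (horizontal log axis) and replicate 2 (vertical log axis), with chromosome I in red, the other chromosomes in grey and a line of equal values. Most points (79.6%) lie below the line, and the point at the upper right is the chromosome V region with values of 184.9 and 121.4.

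The combined list overlapped most regions of both replicates and held many that neither list contained. Of its 7554 regions, 2116 overlapped both replicates, or 28.0% (27.0 to 29.0), 2752 overlapped replicate 1 only and 303 replicate 2 only. A further 2383, or 31.5% (30.5 to 32.6), overlapped neither. The median −log10 q was 10.2 for regions in both, 3.96 and 3.97 for those in replicate 1 or replicate 2 only, and 2.54 for those in neither. In the top 50% of the list by q-value, 55.5% were in both and 3.34% in neither. The 3 strongest regions found in neither replicate were all on chromosome I: from 7086633 to 7087910 (q = 1.93e-08), from 3722499 to 3723905 (q = 3.96e-08) and from 9731242 to 9732286 (q = 4.58e-08). On chromosome I, 46.9% of combined regions were in neither replicate, against 28.9% on the other chromosomes (Fisher's exact test, two-sided p = 4e-31).

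In the other direction, 92.9% of replicate 1 regions and 99.2% of replicate 2 regions overlapped the combined list. The strongest region of both replicates did not. On chromosome V, from 6221388 to 6231164, replicate 1 had its lowest q-value (1.23e-185), and from 6222757 to 6230058 replicate 2 had its lowest (4.18e-122). The nearest combined regions ended at 6214231 on the left and began at 6232849 on the right. The chromosome I region at 15064007 also had no combined overlap. Every other replicate region without one had a −log10 q of at most 5.01 in replicate 1 and 2.95 in replicate 2. These regions were singled out after their values were seen.

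**Figure D2:**
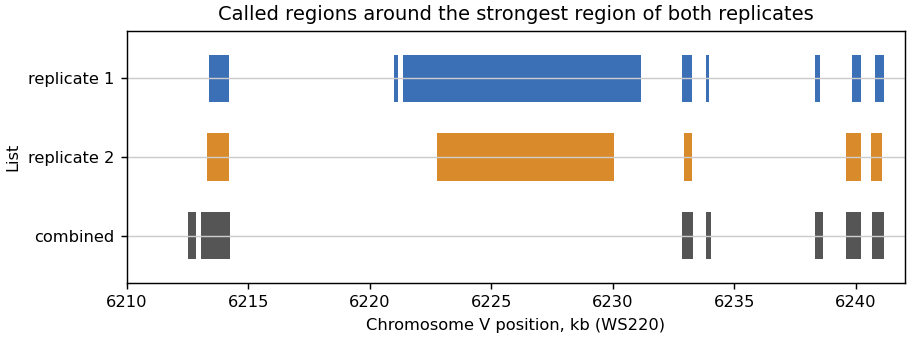
Called regions in the 3 lists along chromosome V (horizontal axis in kb, WS220), each box drawn to scale from start to end. The broad box of 9777 bp in replicate 1 and of 7302 bp in replicate 2 has no counterpart in the combined list, while smaller regions on both sides do.

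Called regions were unevenly spread over the chromosomes when counted per Mb. Gene content, chromatin and mappability were not examined, here or for the X and central shares below. No preference of SEM-4 for a chromosome can therefore be read from the densities. In the combined list, chromosome III carried 99.8 regions per Mb and IV 88.8, against 73.8 on II, 73.7 on I, 62.6 on X and 61.4 on V. Chromosome III was also the densest in replicate 1, with 75.8 per Mb, and in replicate 2, with 43.8. Chromosome I stood differently in the lists: it was the sparsest chromosome in replicate 1, with 41.8 per Mb, and in replicate 2, with 12.3. Its share of the regions was 7.32% in replicate 2 and 11.7% in replicate 1 (Fisher's exact test, two-sided p = 1.1e-09). That test treats the 2 lists as independent although most replicate 2 regions overlap replicate 1, and each list comes from 1 library. Its p therefore does not measure variation between replicates.

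**Figure D3:**
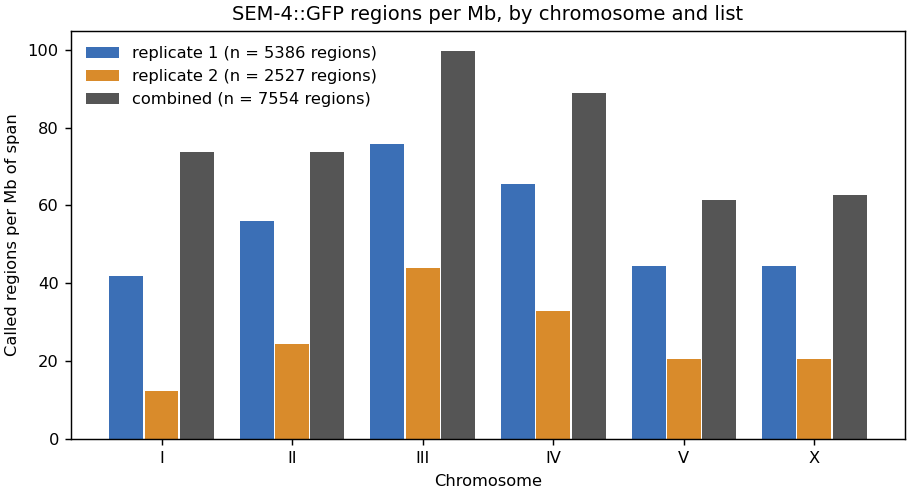
Called regions per Mb of span (vertical axis, from 0) on each chromosome for replicate 1, replicate 2 and the combined list. Chromosome III is highest in each list, at 75.8, 43.8 and 99.8, and chromosome I is lowest in both replicates, at 41.8 and 12.3, but not in the combined list, at 73.7.

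X carried fewer regions than its length predicts. It held 1107 combined regions, 14.7% of the list (13.9 to 15.5), against 17.7% of the span (exact binomial test, two-sided p = 2.7e-12). Its share was 14.6% in replicate 1 and 14.3% in replicate 2. Chromosome V was as sparse as X, so a low density was not particular to X. Regions cluster, which makes the binomial p too small. Over 1 Mb bins the mean was 62.8 ± 13.3 regions on X (SD, 17 bins) and 78.4 ± 31.4 on the autosomes (80 bins), with a permutation p of 0.048. That permutation treats bins as exchangeable, although neighbouring bins hold similar counts and X is 1 chromosome. The p of 0.048 is therefore likely too small as well.

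Along the chromosomes, regions were concentrated in the central 50% of each autosome and on X their share there did not differ detectably from 50%. In the combined list 62.1% of regions (61.0 to 63.2) had their midpoint in the central 50% of the span (exact binomial test against 50%, p = 1.7e-99). The share was 70.7% on V, 66.2% on II, 62.4% on IV, 61.1% on III and 59.8% on I, each above 50% after Benjamini-Hochberg adjustment over the 6 chromosomes (adjusted p of 9.6e-11 or less). On X it was 51.3% (48.4 to 54.2), with an adjusted p of 0.4. The autosomal share of 64.0% exceeded that of X by 12.7 percentage points (Fisher's exact test, two-sided p = 2e-15). The difference was 10.7 points in replicate 1 and 18.9 points in replicate 2. As for the count on X, clustering makes the binomial and Fisher p-values too small. Circular shifts, which keep the clustering, reached a central share over all chromosomes of at most 59.5% (permutation p = 0.001). The contrast of autosomes with X was not tested in that way. Gene content and chromatin, which can differ between arms and centres, were not taken into account.

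**Figure D4:**
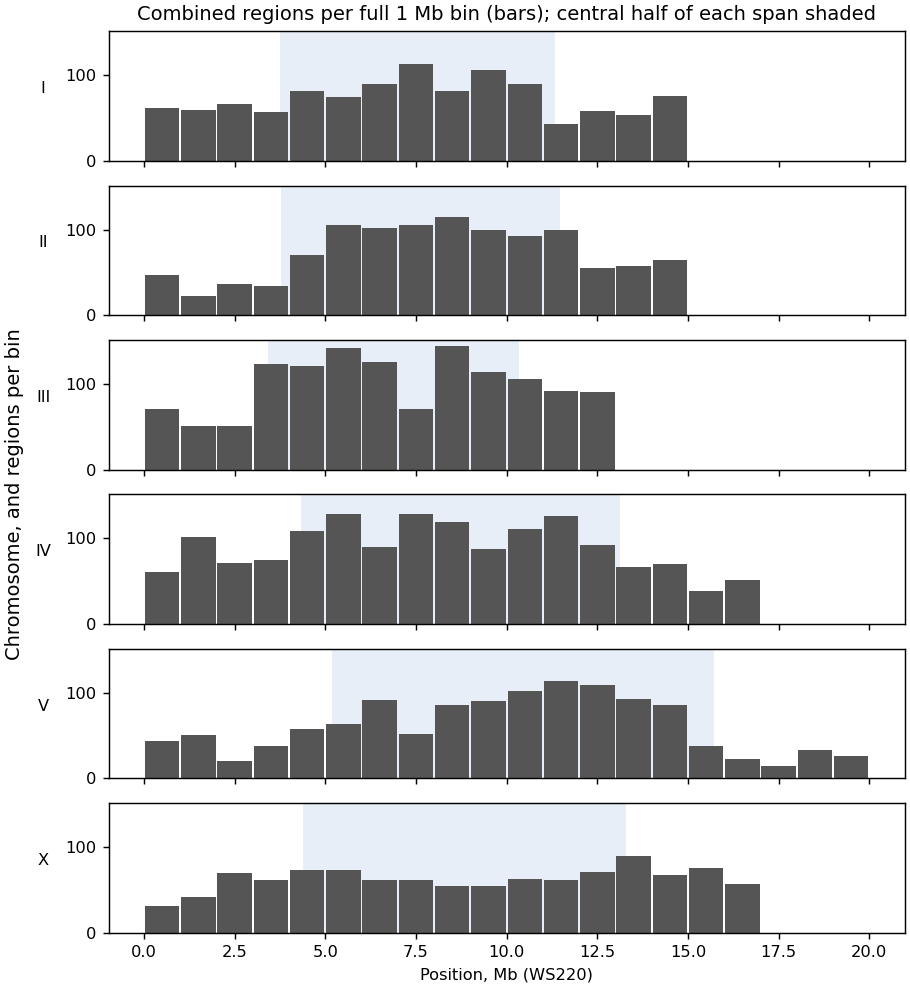
Number of combined regions (vertical axes) in each full 1 Mb bin along the 6 chromosomes (horizontal axis in Mb, WS220), with the central 50% of each span shaded. Central bins held 93.0 ± 25.08 regions (SD, 50 bins) and outer bins 57.2 ± 21.9 (47 bins), while the bars on X show no such rise.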

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

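Each result was recomputed with 1 choice changed at a time. Of 45 values under alternatives, 39 kept their direction, their side of the threshold or their interval. The overlap of replicate 2 with replicate 1 ranged from 68.0%, with both lists at the length of the shorter, to 89.2%, in the top 50% of each list. The share of replicate 1 in replicate 2 ranged from 35.4%, with 50% reciprocal overlap, to 66.6%, with lists of equal length. Both lay above chance in all 7 alternatives. The rank correlation ranged from 0.64 to 0.67. The support of the combined list depended on strength and on chromosome I. The share in both replicates was 55.5% in the top 50% of the list and 30.2% without chromosome I, a removal chosen after the data were seen, and the share in neither was 3.34% and 28.9%. In the counts of occupied 100 kb bins the low share of X turned round, at 17.8% of bins against 17.6% by length (exact binomial p = 0.9), and the central share fell to 51.7% (p = 0.3). Of all 1004 bins, 95.9% held a region, so this measure is close to saturated and says little about density. With either replicate list in place of the combined one, the share on X was 14.3% to 14.6% and the central share 61.8% to 65.4%. No paired analysis was possible because the input libraries have no list of their own here. The alternatives that need an annotation (placement within promoters, and all those for features, gene lists and gene families) were not run. Depth is unknown, so the smaller number of regions in replicate 2 cannot be read as less binding.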

Other observations

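The tests of uniform spacing, of segments and strong regions of chromosome I, and of width within strength classes of the combined list and in replicate 2 were set before their results were seen. The tests of the chromosome V region, of the overall strength of replicate 2, of chromosome I within 6 strength classes, of width within strength classes of each replicate, of the support of chromosome I regions and of the overall width difference on X were chosen after the values were seen.

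Binding regions lay close together. In the combined list, 73.8% had a neighbour within 5 kb, against 56.8% on average and at most 58.8% in 1000 random placements (one-sided permutation p = 0.001, the smallest possible), so uniform placement along the chromosomes is excluded. Part of this closeness may come from broad regions that the caller split. The densest 100 kb bin in both replicates, on chromosome II from 6800000 to 6899999, held 19 regions in replicate 1, 21 in replicate 2 and 23 in the combined list, where the median bin held 7. At the other extreme, long stretches of the combined list with no region, and with none inside them in either replicate, lay on the left arms of II, from 1820282 to 2187783 (367.5 kb), and of V, from 2245150 to 2600626 (355.5 kb), and at the left end of X, up to 324010.

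Regions on X were wider than on the autosomes, with medians of 451 bp and 341 bp in the combined list (permutation p = 1e-05). Lower q-values on X are excluded as the reason. X was wider in 10 of 10 equal classes of −log10 q in the combined list, and also in 10 of 10 in each replicate. The lists hold no fold enrichment, so stronger binding as such could not be tested. The median −log10 q on X and on the autosomes was 3.52 and 3.99 in the combined list, 3.18 and 3.26 in replicate 1, and 3.42 and 3.35 in replicate 2, so X was not weaker in every list. A difference in replicate 1 alone is excluded too, since the gap to the pooled autosomes was 128.5 bp in replicate 2 (permutation p = 1e-05). Not every autosome was narrower there: in replicate 2 the median was 559 bp on chromosome I and 542.5 bp on X. In replicate 1 and the combined list, X had the widest median of all chromosomes. Base composition and mappability could still account for the width difference and were not tested. The design gives no group with which to test a biological explanation.

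Chromosome I behaved unlike the others when lists were compared. For overlapping regions, the median ratio of replicate 2 to combined −log10 q was 0.27 on I and 0.40 to 0.44 on the other chromosomes (permutation p = 1e-05), which a weaker or shallower replicate 2 as a whole would not give. The ratio for replicate 1 was also low, 0.55 on I and 0.63 to 0.69 elsewhere (permutation p = 1e-05), so the gap to the combined list was not particular to replicate 2. Between the replicates themselves the difference was smaller: the ratio of replicate 2 to replicate 1 was 0.61 on I and 0.66 to 0.77 elsewhere (permutation p = 0.0024). That ratio covers only regions called in both replicates. Of the replicate 1 regions, 27.6% on I overlapped replicate 2, against 37.9% to 48.0% elsewhere, so the ratio may understate the difference on I. A change in 1 part of the chromosome is excluded, since 10 of 10 equal segments of I lay below every other chromosome's median, with 8 to 35 pairs in each. A candidate explanation is a control scaling set chromosome by chromosome in the calling, which predicts a shift at all strengths. The test set for it, on the 2518 strongest combined regions, gave 0.27 on I against 0.36 to 0.40, but it decides nothing, since 98.9% of the pairs on I lie in that subset. A later test split each replicate list into 3 classes of its own −log10 q, and I lay below every other chromosome in 6 of 6 classes (permutation p of 0.00049 or less). The overall ratios were known by then, and any shift of the whole chromosome in the calling or the combining of lists would give this, so control scaling stays open. Of the combined regions with a −log10 q of 5 or more, 23 of 415 on I and 7 of 2405 elsewhere were in neither replicate list (Fisher's exact test, p = 3.2e-14), and no biological explanation was tested.

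The chromosome V region that led both replicates had no overlap in the combined list. An upper limit on width is excluded, since 2 combined regions were wider than its 9777 bp. A candidate explanation is a q-value too small to be stored as a double-precision number, which ends at a −log10 of 323.3, or 307.7 at full precision. Such a value alone would not remove a region, so a further step that drops it is also needed. Whether there was such a step could not be examined. The replicate values of 184.9 and 121.4 sum to 306.3, and the ratios seen in the 14 next regions of replicate 1 put the expected combined value at 327.8, with a range of 225.8 to 481.2. Of the 14 values, 7 lay above 323.3 and 8 above 307.7. The 2 highest came from chromosome I, where combined values are high for their replicate values. Without them the expected value was 308.6, below 323.3 but above 307.7, with a range of 225.8 to 464.2. Of the 12 values, 5 lay above 323.3 and 6 above 307.7. The range lies on both sides of either limit with and without the chromosome I regions, so this explanation stays open.

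The second strong replicate region without a combined overlap, at the right end of chromosome I, had a −log10 q of 41.2 in replicate 2. This is far below either storage limit, so the explanation left open for the chromosome V region does not extend to it. Regions under 50 bp made up 306 of the replicate 1 list, 318 of the combined list and 4 of the replicate 2 list. In replicate 1, the 306 had a median −log10 q of 2.37, and 16 were 1 bp wide.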
